A study of Rattus norvegicus with 105 samples.

How the data were processed

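Primary hepatocytes of female Sprague-Dawley rats, all of one commercial cell lot, had been cultured in collagen-coated 96-well plates and exposed for 24 hours to nitromethane (NM), nitroethane (NE) or 1-nitropropane (1NP), each at 8 concentrations. Per the labels the RNA was profiled with TempO-Seq, a targeted assay in which pairs of short detector oligonucleotides are joined on the RNA of each gene, amplified and sequenced. The panel is named in the labels as a human whole-transcriptome panel, but the gene symbols of the table are written as rat symbols, and 15980 of the 20946 symbols were found in a rat gene table (assembly GRCr8). No chromosome positions of probes were used. There were 105 libraries in 35 groups of 3. Of these, 72 libraries formed set 1 (NM, NE, medium, DMSO, benzo[a]pyrene, CITCO, rifampin and WY-14643) and 33 formed set 2 (1NP, medium, DMSO and WY-14643), by the prefix of the library names.

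The table deposited by the authors holds raw read counts per detector probe, 22253 probes by 105 libraries, with no normalization applied. Per the labels the processing of the reads used FastQC, Bowtie, R 3.5.3 and DESeq2 1.28.1, with no role given for each; the genome build and the aligner version are not given in the sources used here. Some labels differed from the protocol text. The nitroalkane concentrations carry a µM unit in the sample titles and mM in the protocol, and mM was used. DMSO is titled 0.5 and described as 0.2% in the protocol, and WY-14643 of set 2 is titled 50 µM while its library names say 100. Rifampin stands in the labels but not in the protocol. The labels do not say whether the nitroalkane wells held DMSO. A formaldehyde control named in the protocol was not analysed here. The labels speak of 3 biological replicates, but the cells came from one lot, so the p-values below measure the spread between wells and not between animals.

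Total counts per library ran from 5475419 to 11122665 (median 8680678), and 13287 to 21627 probes per library had a count (median 13792). A median of 0 across libraries was found for 8606 probes, and 343 probes had no count in any library. Between any 2 libraries of a group the counts differed by more than counting error (smallest chi-square per degree of freedom 2.82), so no library was a copy of another of its group. Library totals set the floor of detection for single probes, with counting error only.

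Counts were analysed with edgeR 4.0.16 in R 4.3.3. Probes were kept by filterByExpr at its defaults (minimum count 10, minimum total count 15), libraries were scaled by TMM factors, dispersions were estimated with estimateDisp (robust), and each contrast was tested with the quasi-likelihood F test (glmQLFit robust, glmQLFTest). A probe was called at a Benjamini-Hochberg adjusted p under 0.05 over all probes kept in that fit. Each nitroalkane was fitted with its 8 concentrations and the DMSO libraries of its set (27 libraries), and the contrasts were each concentration against DMSO and a slope over the rank of the concentration, with DMSO as rank 0. The reference compounds and medium of set 1 (24 libraries) and of set 2 (9 libraries) were fitted together with their DMSO libraries. NM and NE, both in set 1, were compared directly at each concentration (6 libraries a fit). 1NP lay in the other set, so its effect against its own DMSO was compared with the effect of NM or NE against theirs (12 libraries a fit). DMSO of set 2 was compared with DMSO of set 1. Standard errors of log2 changes are approximate, the absolute log2 change divided by the square root of F. Intervals of 95% for differences between compounds use that standard error and the normal quantile.

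Before the data were examined, 24 gene lists were fixed. Most cover pathways of liver toxicology: AhR targets, CAR and PXR targets, PPARα targets, NRF2 targets, p53 and DNA damage, ATF4 and amino acid response, ER chaperones and unfolded protein response, heat shock, metallothioneins, hypoxia and glycolysis, cholesterol synthesis, fatty acid and triglyceride synthesis, bile acid synthesis and transport, hepatocyte secreted proteins and identity, inflammation and acute phase, cell cycle, oxidative phosphorylation, and aldehyde, one-carbon and nitroalkane metabolism. A further 6 are markers of stellate cells, Kupffer cells, endothelium, cholangiocytes, lymphocytes and erythroid cells. Lists with at least 3 probes in a fit were tested, 21 in all, by camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a contrast. The same test with an estimated correlation is given beside it. Members were counted as called over all probes, and again adjusted over the list alone. A gene with several probes counts once for each probe.

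Named genes follow a rule fixed before the data were examined: adjusted p under 0.05, a mean of at least 10 CPM (counts scaled to a common library total) over the libraries compared, and every library of one group above every library of the other. Under it come the 10 largest rises and falls for each nitroalkane at 10 mM, the 5 largest rises and 3 largest falls for each reference compound, the 3 largest each way for medium and for the lowest concentration with more than 5 calls, and the 5 largest each way between nitroalkanes at 10 mM. Up to 4 called members with the smallest p stand for each list. A fixed set of marker genes was looked up whatever their result, and the text gives a part of those values. Cyp2b1 and Hspa1a, both tested in set 1, have no value in the text. Of these markers, Cyp3a23-3a1 has no probe in the table and Cyp7a1 did not pass the filter. Changes in text are log2 changes ± SE, levels are mean CPM ± SD, and each group has n = 3 libraries.

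Libraries that stood apart from their group were found by 2 measures: a median correlation of log2 CPM with the others of its group under 0.95 (probes over 5 CPM, and lowest of its group), or more than 1.5 times the median number of detected probes. The chosen alternatives were DESeq2 size factors, no filter, the DESeq2 1.42.0 Wald test, medium as control, only the libraries compared, the replicate number as a block, trends by an omnibus test or without 10 mM, and leaving out each library in turn. After seeing the data, 8 more were added: the 0.003 mM libraries as control, with and without a block, the trend without a control, 4 settings without the libraries that stood apart, and medium as control for the lists. Scaling by DESeq2 size factors moved the median change of all probes by at most 0.021.

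Replicate numbers were checked for pairing by correlating the residuals of libraries that share a number. In 33 comparisons these correlations ran from -0.69 to 0.59, and in 1, benzo[a]pyrene against DMSO, every pair was over 0.1 (0.16 to 0.53). With the replicate number as a block that comparison gave 1161 probes, against 1110 without. For 1NP against DMSO no paired analysis was possible because the 1NP libraries are numbered 1 to 3 and the DMSO libraries of their set 4 to 6.

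The functions were tested on simulated data. Counts were drawn from the mean of each probe over all libraries of the fit and its fitted dispersion. Some probes were changed by 1.5-, 2- or 4-fold. No other group difference and no library standing apart was simulated, so the numbers hold for that simpler setting. For NE at 10 mM against DMSO, 3 of 67 probes changed 1.5-fold, 31 of 67 changed 2-fold and 54 of 66 changed 4-fold were called, with 3 wrong calls among 91. The fits between compounds at 10 mM called fewer. NM against NE called 4 of 67 at 2-fold and 39 of 66 at 4-fold, the 1NP effect against the NM effect 1 of 67 and 30 of 66, and the 1NP effect against the NE effect 3 of 67 and 37 of 66. Among 20 simulated lists of 20 probes, the 1 list shifted by 0.5 was called and none of the others was.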

Results

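Gene expression was measured with TempO-Seq in primary hepatocytes of female Sprague-Dawley rats after 24 hours of exposure to a nitroalkane or a reference compound. The nitroalkanes NM (nitromethane), NE (nitroethane) and 1NP (1-nitropropane) carry 1 nitro group on chains that lengthen by 1 carbon each, and each was given at 8 concentrations from 0.003 to 10 mM. Set 1 also held medium, DMSO, benzo[a]pyrene at 50 µM, CITCO at 10 and 20 µM, rifampin at 20 and 40 µM and WY-14643 at 50 µM. Set 2 held 1NP, medium, DMSO and WY-14643. Each of the 35 groups had n = 3 libraries, 105 in all. Total counts per library ran from 5475419 to 11122665, with a median of 8680678, and a median of 13792 of the 22253 probes had a count. In DMSO replicate 1 of set 1 a count of 3 corresponds to 0.355 CPM, the unit of levels in the text (counts scaled to the library total).

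There were 6 libraries that stood apart from their own group. NE at 10 mM replicate 2 had counts in 21627 probes. NM replicate 3 at 10 mM, replicate 1 at 3 mM and replicate 1 at 1 mM, 1NP replicate 3 at 10 mM and NE replicate 3 at 0.01 mM had median correlations of 0.880, 0.881, 0.927, 0.896 and 0.941 with the others of their group. They were kept in the counts that follow, and results without them are given where they moved a count by more than 1.5 times.

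Medium and DMSO were compared to see how the 2 controls differ. In both sets the medium wells lay in plate row A and the DMSO wells in row B, so vehicle and row are joined here. In set 1, medium cells had more Car3 (carbonic anhydrase 3; 3.19 ± 0.41, adjusted p = 7.26e-05) than DMSO cells. They had less Hdc (histidine decarboxylase; -3.21), less of the chemokine Cxcl10 (-2.52 ± 0.20) and less Cyp4a1, a fatty acid hydroxylase and PPARα target (-2.49 ± 0.26). Lgals4 (1.97) and Crip1 (1.73) were higher. In set 2 the largest rises were Car3 (3.04), Bcl2l1 (2.33) and Cep295nl (2.15), and the largest falls Cps1, the first enzyme of the urea cycle (-3.23), Cxcl10 (-2.62) and Cyp4a2 (-2.37). Of the ATF4 and amino acid response list, 16 of 34 probes rose in medium of set 1 (25 adjusted over the list alone; adjusted p = 0.000471 with an estimated correlation), among them Ddit3 (0.96) and Trib3 (0.92). PPARα targets fell in 17 of 28 (18 fell and 1 rose adjusted over the list alone; adjusted p = 0.00345 with an estimated correlation), ER chaperones in 8 of 16 (0.00345), inflammation genes in 12 of 16 with 2 rising (0.00145), hepatocyte genes in 18 of 27 (0.00345) and metallothionein probes in 4 of 4 (0.00136). Set 2 gave 20 of 28 PPARα targets, 10 of 16 ER chaperones and 4 of 4 metallothionein probes lower in medium, with 15 of 34 ATF4 list probes higher and 1 lower (adjusted p = 0.0288, 0.0117, 0.0288 and 0.0117 with an estimated correlation). Of 11 lists called in set 2, 5 lost the call with an estimated correlation: cholesterol synthesis (adjusted p = 0.109), CAR and PXR targets (0.116), oxidative phosphorylation (0.144), aldehyde and one-carbon metabolism (0.101) and stellate cell markers (0.144). In all, 855 probes differed in set 1 (386 higher in medium, 469 lower) and 2769 in set 2 (1334 and 1435). The set 1 count was 538 without DMSO replicate 1, 565 without DMSO replicate 2 and 510 without medium replicate 3. The set 2 count was 1561 without DMSO replicate 4, 1735 without DMSO replicate 6 and 1674 without medium replicate 5.

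Benzo[a]pyrene, an agonist of the aryl hydrocarbon receptor (AhR), was included as a reference for that receptor. It raised Cyp1b1 by 10.39 ± 0.23 (adjusted p = 1.34e-24), from 0.458 ± 0.101 CPM in DMSO, near the floor of 3 counts, to 663 ± 42.3 CPM. Cyp1a2 rose by 7.62 ± 0.33, Cyp1a1 by 5.60 ± 0.29, the aldehyde dehydrogenase Aldh3a1 by 5.13 ± 0.25 and the glutathione transferase Gsta2 by 5.05 ± 0.24. AhR targets rose in 7 of 7 (7 over the list alone as well; list adjusted p = 9.86e-133). NRF2 targets rose in 16 of 28 probes (18 adjusted over the list alone), with the quinone reductase Nqo1 at 4.07 ± 0.15. In the p53 list 9 of 21 rose (10 rose and 1 fell adjusted over the list alone), among them Mdm2 (0.73 ± 0.09), Plk2 (1.08) and the cell cycle inhibitor Cdkn1a (1.19, adjusted p = 0.00375). Against medium Cdkn1a differed by 0.55 (adjusted p = 0.152). CAR and PXR targets rose in 5 of 9, among them Cyp3a9 (2.59) and Ephx1 (1.61), and cholesterol synthesis fell in 15 of 21 (18 adjusted over the list alone). The largest falls were Crct1 (-4.08), A2m (-2.57) and the neuropeptide gene Calcb (-2.00 ± 0.12). In all, 1110 probes passed (496 up, 614 down), and 2382 against medium.

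CITCO and rifampin, ligands of the human CAR and PXR receptors, were included as references for those receptors. CITCO at 10 µM raised Cyp1b1 (4.95 ± 0.28), Cyp1a2 (2.42 ± 0.32, adjusted p = 0.00236) and Gsta2 (1.44 ± 0.22). Cyp1b1 was near the floor of 3 counts in DMSO (0.458 CPM), so the size of its rise is uncertain. Cyp1a2 was higher at 10 µM (34.5 ± 8.71 CPM) than at 20 µM (17.6 ± 6.61 CPM). The 10 µM wells lay in row D, columns 10 to 12, beside benzo[a]pyrene in row C of the same columns. The 20 µM wells lay in row G, columns 1 to 3. Concentration and plate place are therefore joined here, and an influence of neighbouring wells was not tested. At 20 µM CITCO raised Gsta2 by 2.95 ± 0.22, from 19.7 ± 2.42 to 154 ± 50.5 CPM. Gsta5 (2.57), Mt2A (1.13 ± 0.16) and Por, the electron donor of cytochromes P450 (0.81 ± 0.09), also rose there. At 20 µM, Cyp1a2 rose by 1.45 and Cyp1a1 by 1.44 (0.50 against medium). Nexn (1.59, and 0.11 against medium), Mmp2 (1.21) and Nefl (0.82) also rose at 10 µM, where Hamp fell (-1.63, and -0.21 against medium). Cxcl10 was at -1.10 and C4bpb at -0.98 against DMSO but at 1.42 and 1.49 against medium, and Mmp2 and Nefl were at -0.49 and -0.38 without passing. At 20 µM the falls were Hamp (-1.64, and -0.22 against medium), Krt20 (-1.48) and the fatty acid binding protein Fabp1 (-1.46, but 0.97 against medium). AhR targets rose in 2 of 7 at 10 µM (5 adjusted over the list alone; adjusted p = 5.1e-07 with an estimated correlation) and in 2 of 7 at 20 µM (3 rose and 1 fell adjusted over the list alone; adjusted p = 0.212 with an estimated correlation). CAR and PXR targets at 20 µM rose in 2 of 9 (3 rose and 1 fell adjusted over the list alone; adjusted p = 0.232 with an estimated correlation). NRF2 targets at 20 µM rose in 2 of 28 (12 adjusted over the list alone; adjusted p = 0.00769 with an estimated correlation). CITCO gave 18 probes at 10 µM (11 up, 7 down) and 102 at 20 µM (45 up, 57 down), and 312 and 1785 against medium. At 10 µM the count was 10, 4 and 9 without DMSO replicates 1, 2 and 3 and 11, 7 and 8 without CITCO replicates 1, 2 and 3. At 20 µM it was 37 and 66 without DMSO replicates 2 and 3, and 63 and 58 without CITCO replicates 1 and 2. Leaving out 1 library also ended calls of single genes, with their values little moved. At 10 µM these were Mmp2 without any 1 of the 6 libraries (1.09 to 1.40), C4bpb without any but DMSO replicate 3 (-1.05 to -0.87), Nexn and Gsta2 without DMSO replicate 2 (1.48 and 1.39) or 3 (1.46 and 1.38), Nefl without DMSO replicate 2 (0.74) and Cxcl10 without CITCO replicate 3 (-0.89). At 20 µM they were Fabp1 without any 1 library (-1.57 to -1.27), Krt20 without any but DMSO replicate 1 (-1.53 to -1.29), Cyp1a2 without any but CITCO replicate 3 (1.09 to 1.66) and Cyp1a1 without replicate 2 or 3 of either group (at most 1.36).

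Rifampin at 20 µM raised Cnn1 (1.71), Mmp2 (1.67), Nexn (1.65) and Tagln (1.39) against DMSO. Against medium these were at 0.70, -0.04, 0.17 and 0.13, and none passed (adjusted p = 0.551, 0.989, 0.934 and 0.958). At 40 µM the largest rises were Mmp2 (1.53), Cnn1 (1.45), Fblim1 (1.42), Aif1l (1.24) and the actin gene Acta1 (1.18), and the largest falls Hdc (-1.82), Plg (-1.71) and Serpina3m (-1.59). Against medium only Hdc of these passed, in the other direction (1.39, adjusted p = 0.0368), with the rises at -0.17, 0.44, -0.01, 0.42 and 0.40, Plg at 0.14 and Serpina3m at -0.25. At 20 µM several genes had the other sign against medium, and none of these passed. Car3, up by 2.25, was at -0.94, and Hdc, down by 2.06 on the log2 scale, was at 1.15. The lipase Lpl (-1.93) was at 0.33 and Bhmt (-1.93) at 0.39. CAR and PXR targets fell in 3 of 9 at 20 µM (5 adjusted over the list alone; adjusted p = 0.0564 with an estimated correlation) and in 4 of 9 at 40 µM (5 adjusted over the list alone; adjusted p = 0.0467 with an estimated correlation). Cyp3a9, a PXR target, fell by 0.79 at 40 µM (adjusted p = 0.00812). Rifampin called 347 probes at 20 µM (133 up, 214 down) and 204 at 40 µM (66 up, 138 down), and 33 and 401 against medium. At 20 µM the count was 122 and 174 without DMSO replicates 1 and 2, and 204 and 107 without rifampin replicates 1 and 3. At 40 µM it was 97 and 93 without those DMSO replicates, and 79 and 113 without rifampin replicates 1 and 3. Without any 1 of these 4 libraries the calls of Lpl at 20 µM (-1.89 to -1.55) and of Cnn1 and Plg at 40 µM (1.26 to 1.47 and -1.63 to -1.53) ended, and that of Serpina3m at 40 µM ended without rifampin replicate 1 (-1.43).

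WY-14643, an agonist of PPARα, raised enzymes of fatty acid oxidation. In set 1 Ehhadh, a peroxisomal β-oxidation enzyme, rose by 4.17 ± 0.30 (adjusted p = 1.68e-10), Fabp1 by 4.15 ± 0.33, the acyl-CoA thioesterase Acot1 by 4.07 ± 0.38, Pdk4, which limits glucose oxidation, by 3.37 ± 0.25 and Fabp3 by 3.32. In set 2 Fabp1 rose by 4.88 ± 0.22, Acot1 by 4.77 ± 0.22, Ehhadh by 4.09 ± 0.24, Fabp3 by 3.40 and Pdk4 by 2.49. PPARα targets rose in 25 of 28 probes in set 1 (26 adjusted over the list alone) and in 20 of 28 in set 2 (27 adjusted over the list alone). The largest falls were Mt2A (-1.88), Bhmt (-1.76) and A2m (-1.67) in set 1, and Cps1 (-1.74), Krt20 (-1.54) and Plg (-1.43) in set 2. Against medium the set 1 falls did not pass, with Mt2A at -0.35, Bhmt at 0.56 and A2m at -0.49. In set 2 Krt20 passed in the same direction (-1.56), and Cps1 (1.5, adjusted p = 0.00445) and Plg (0.88, adjusted p = 0.0193) in the other. In all 591 probes passed in set 1 (284 up, 307 down) and 104 in set 2 (77 up, 27 down), against 1954 in set 2 with medium as control. The set 1 count was 280 and 296 without DMSO replicates 1 and 2, and 312, 246 and 964 without WY-14643 replicates 1, 2 and 3. The set 2 count was 67 without DMSO replicate 4.

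Each concentration of each nitroalkane was compared with DMSO of its set to follow the response over dose. By the wells in the library names each concentration lay in 1 plate row, from row A at 0.003 mM to row H at 10 mM. DMSO lay in row B. Concentration and row are therefore joined in these comparisons, at 10 mM too, and in the slopes. At 0.003 mM, the lowest, NM raised Car3 (3.27), Nefm (2.27) and Lgals4 (1.85) and lowered Hdc (-3.44), Cxcl10 (-2.89) and C4bpb (-2.69). NE raised Car3 (3.18), Fblim1 (1.84) and Mmp2 (1.83) and lowered Cxcl10 (-2.56), Lpl (-2.45) and Bhmt (-2.35). 1NP raised Car3 (3.02), Bcl2l1 (2.62) and Lgals4 (2.53) and lowered Cps1 (-2.80), Ccl2 (-2.48) and the clotting factor F9 (-2.45). The Cps1 call ended without any 1 of the 6 libraries (-3.33 to -2.59), and that of Ccl2 without DMSO replicate 5 or 1NP replicate 1 or 2 (-2.46 to -2.29). Against medium none of these probes passed, with Car3 at 0.09, 0.00 and 0.01, Lgals4 at -0.11 for NM and Cps1 at 0.46 for 1NP. From the lowest concentration to the highest, NM called 474, 124, 216, 248, 384, 251, 83 and 879 probes against DMSO. NE called 366, 330, 330, 424, 652, 346, 750 and 3557, and 1NP 2414, 49, 124, 616, 124, 180, 69 and 263. With medium as the control the counts were 0, 0, 0, 0, 0, 1, 284 and 81 for NM, 0, 2, 0, 0, 4, 27, 1423 and 4197 for NE, and 1, 23, 0, 2, 0, 8, 27 and 1237 for 1NP. Leaving out 1 library moved each count against DMSO, except that of NE at 10 mM, by more than 1.5 times. NM at 3 mM fell to 20 without DMSO replicate 1, NE at 3 mM to 356 without DMSO replicate 2 and 1NP at 0.003 mM to 898 without its replicate 1, while 1NP at 1 mM rose to 1858 without its replicate 3.

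**Figure D1:**
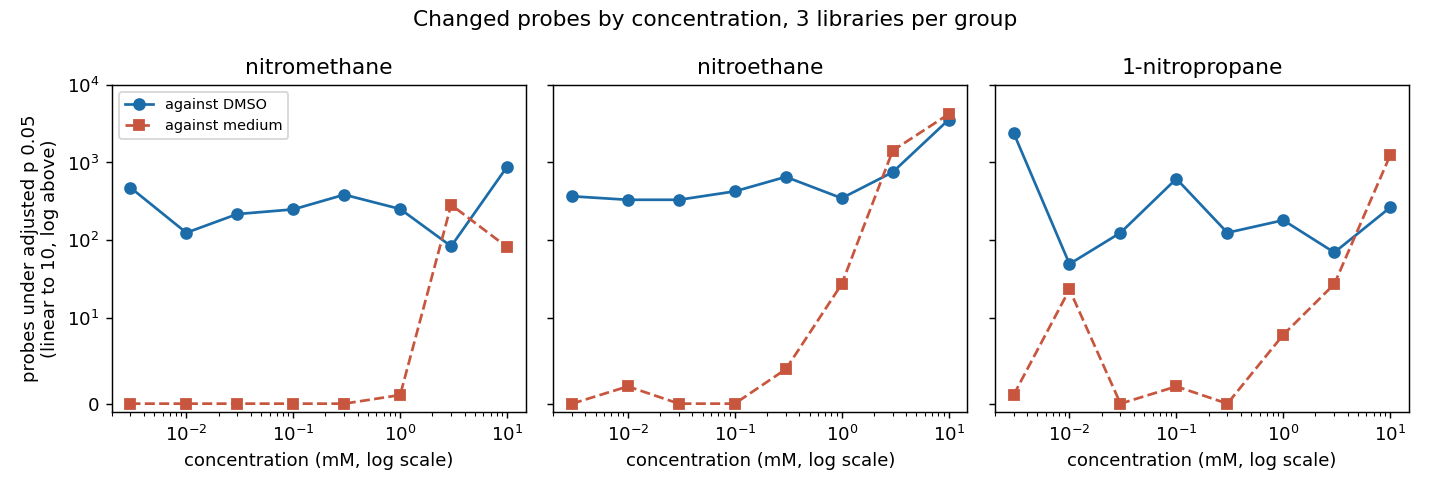
Number of probes called (edgeR, adjusted p under 0.05; axis linear to 10 and log above) at each concentration (mM, log axis) of NM, NE and 1NP, with DMSO (solid lines) or medium (dashed lines) of the same set as the control. Against DMSO 474, 366 and 2414 probes were called at 0.003 mM, and against medium 0, 0 and 1.

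NM at 10 mM lowered cholesterol synthesis against both controls. Of 21 enzymes and regulators, 12 fell against DMSO (15 adjusted over the list alone; adjusted p = 0.00508 with an estimated correlation) and 6 against medium (13 adjusted over the list alone; adjusted p = 0.0112 with an estimated correlation). Cyp51 fell by 0.71 ± 0.09 (-0.70 against medium, adjusted p = 0.0014), Insig1 by 1.24 ± 0.17 (-1.08 against medium, adjusted p = 0.00528) and Fdft1 by 0.71 (-0.64 against medium, adjusted p = 0.00528). The actin-binding Pfn1 rose by 2.07 ± 0.45 against DMSO, from 5.08 ± 1.85 to 22.9 ± 3.39 CPM, and by 2.01 ± 0.44 against medium (adjusted p = 0.0305). In an edgeR fit of only the NM and DMSO libraries compared it did not pass (2.09 ± 0.33, adjusted p = 0.0524). The cyclin Ccng1, a p53 target, rose by 2.43 ± 0.48 (3.19 against medium, adjusted p = 0.0176) at 5.66 CPM. In replicates 1, 2 and 3 at 10 mM it measured 6.93, 8.52 and 2.55 CPM with NE and 10.8, 21.4 and 12.1 CPM with 1NP.

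The largest rise of NM at 10 mM against DMSO was Car3 (3.41 ± 0.25, adjusted p = 1.31e-08), which did not pass against medium (0.23, adjusted p = 0.602). Trps1 (2.28), Mmp2 (2.24 ± 0.24), Inhba (2.06), Tnc (1.98), Adgrv1 (1.95), Lmcd1 (1.95), Nexn (1.93) and F3 (1.89) completed the 10 with Pfn1. Of these 10 only Pfn1 passed against medium, where Trps1 was at 1.39 (adjusted p = 0.0952), Mmp2 at 0.55, Inhba at 0.62, Tnc at 0.43, Adgrv1 at 1.11, Lmcd1 at 0.57, Nexn at 0.46 and F3 at 0.67. Adgrv1 did not pass without NM replicate 3 (0.93), nor without any 1 of the DMSO libraries (1.92 to 2.04). The largest falls were Fabp1 (-3.56 ± 0.40; -1.12 against medium, adjusted p = 0.184), Cxcl10 (-2.89 ± 0.26; -0.36 against medium), the iron hormone gene Hamp (-2.70), Bhmt (-2.70), Lpl (-2.33), Ccl20 (-2.24), Hdc (-2.22; 1.00 against medium), Cxcl9 (-2.16), Cyp4a2 (-2.09 ± 0.24) and Slc27a2 (-2.09). None of these falls passed against medium, where Hamp was at -1.27 (adjusted p = 0.214), Bhmt at -0.38, Lpl at -0.06, Ccl20 at -0.55, Cxcl9 at -0.23, Cyp4a2 at -0.29 and Slc27a2 at -0.22. PPARα targets fell in 16 of 28 probes against DMSO (21 adjusted over the list alone; adjusted p = 0.00484 with an estimated correlation) and in 0 of 28 against medium (5 fell and 1 rose adjusted over the list alone). Hepatocyte genes fell in 17 of 27 against DMSO (20 fell and 1 rose adjusted over the list alone), among them Arg1 (-1.15), Fbp1 (-1.48) and the fibrinogen chain Fgg (-1.52). Against medium 0 fell and 1 rose, with Fgg at 0.11. Inflammation genes fell in 7 of 16 with 2 rising, CAR and PXR targets in 5 of 9, metallothionein probes in 3 of 4 and bile acid genes in 2 of 10, and each of these lists was called with an estimated correlation too. Adjusted over the list alone the falls were 9 (with 2 rises), 5, 4 and 4. Against medium these 4 lists held 0 called members. The ATF4 list rose in 10 of 35 (12 rose and 1 fell adjusted over the list alone), with Ddit3 at 0.90 and Wars at 0.82, and in 0 of 35 against medium, where Ddit3 was at -0.04 and the list test pointed down.

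Further lists of NM at 10 mM were called against DMSO by the preset correlation alone. They were ER chaperones (0 rose and 4 fell of 16; adjusted p = 0.1 with an estimated correlation), aldehyde and one-carbon metabolism (0 and 5 of 16; adjusted p = 0.0759), fatty acid synthesis (0 and 1 of 15; adjusted p = 0.0739), oxidative phosphorylation (0 and 0 of 21; adjusted p = 0.45), NRF2 targets (1 and 3 of 27; adjusted p = 0.488) and cholangiocyte markers (2 and 0 of 5; adjusted p = 0.1). Adjusted over the list alone the rises and falls were 1 and 7, 1 and 7, 0 and 3, 0 and 0, 1 and 5, and 3 and 0. Stellate cell markers rose in 1 of 3, Tagln at 1.70 (0.45 against medium). Not called were the p53 list (4 rose of 22), AhR targets (1 fell of 6; median 0.12, mean -0.02), heat shock (1 rose of 15), hypoxia (4 rose of 27), cell cycle (0 of 21) and Kupffer cell markers (0 of 4; median 0.04, mean -0.09). Hspa5 (-0.25, adjusted p = 0.431), Cyp1a1 (0.30) and Cdkn1a (0.11, adjusted p = 0.795) did not pass, and Mdm2, a p53 target, rose by 0.35 (0.19 against medium, adjusted p = 0.366). In all 879 probes passed (481 up, 398 down), against 81 with medium as control. The count was 508 and 498 without DMSO replicates 1 and 2 and 516 without NM replicate 3, and 1376 without the NM libraries that stood apart at 10, 3 and 1 mM.

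NE at 10 mM raised chaperones of the endoplasmic reticulum and lowered cholesterol synthesis and inflammation genes. Hspa5, the main chaperone of that compartment, rose by 3.37 ± 0.27 (adjusted p = 7.08e-10), from 27.7 ± 2.47 to 301 ± 41.5 CPM. The chaperone Hsp90b1 rose by 2.73 ± 0.15, Creld2 by 2.75 ± 0.21 and Dnajc3 by 1.94 ± 0.15. ER chaperones rose in 14 of 16 probes (15 adjusted over the list alone; adjusted p = 0.000846 with an estimated correlation) and in 16 of 16 against medium, where Hspa5 rose by 4.24. At 3 mM 11 of 16 rose (14 adjusted over the list alone), with Dnajc3 at 1.53 ± 0.15 and Creld2 at 1.37, and Hspa5 was at 0.53 (adjusted p = 0.258) against DMSO but at 1.40 (adjusted p = 0.000951) against medium.

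The largest rise at 10 mM was Cyp4b1 (5.75 ± 0.58, adjusted p = 2.52e-08), from 0.456 ± 0.216 CPM, near the floor of 3 counts, to 26.5 ± 3.82 CPM. The others were Shc4 (3.52; 1.92 against medium), the secretory transcription factor Bhlha15 (3.22 ± 0.24), Tsku (3.16 ± 0.17), Selenom (3.13), Cyp1a1 (2.92 ± 0.27; 1.99 against medium), Akr1c19 (2.91) and Nefm (2.76; 0.81 against medium, adjusted p = 0.0598). The largest falls were Crct1 (-4.94 ± 0.44), Hdc (-4.56, and -1.35 against medium, adjusted p = 0.0883) and Calcb (-4.39 ± 0.20, from 599 ± 10.5 to 29.3 ± 7.08 CPM). Next were the protease inhibitor A2m (-4.26 ± 0.22), Bcam (-3.75) and the chemokines Ccl2 (-3.56 ± 0.37), Ccl20 (-3.48, and -1.80 against medium) and Cxcl3 (-3.41 ± 0.28). Bace2 (-3.30) and Plbd2 (-3.26 ± 0.16) completed the 10. With NE Crct1 was at 1.73 ± 2.31 CPM and Hdc at 0.95 ± 0.96 CPM. Replicate 2, with counts in 21627 probes, was highest for Bcam (0.99, 3.99 and 0.444 CPM in replicates 1, 2 and 3) and Bace2 (1.86, 8.26 and 1.78). The sizes of these 4 falls are therefore uncertain. Inflammation genes fell in 12 of 16 (14 adjusted over the list alone, adjusted p = 1.57e-05 with an estimated correlation). Among them were the acute phase gene Orm1 (-2.04) and Tnfaip3 (-1.67). Medium of set 1 also had 12 of 16 lower than DMSO. Against medium A2m fell by 3.17 (edgeR adjusted p = 4.53e-11) and Ccl2 by 2.49 (3.46e-06) on the log2 scale. Counts against medium are not given here for the inflammation, cholesterol synthesis and cell cycle lists. Cholesterol synthesis fell in 17 of 21 (20 adjusted over the list alone; adjusted p = 0.00666 with an estimated correlation), with Cyp51 at -2.02 ± 0.13, Acat2 at -1.77 and Fdft1 at -1.20. Cell cycle genes fell in 15 of 21 (16 adjusted over the list alone; adjusted p = 0.054 with an estimated correlation), among them Ccnd1 (-1.86), the helicase subunit Mcm3 (-1.58) and Mki67 (-1.50).

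NRF2 targets rose in 14 of 28 probes of NE at 10 mM with 1 falling (15 and 1 adjusted over the list alone; adjusted p = 0.054 with an estimated correlation). They included the transporter Abcc4 (2.31; 1.44 against medium), Akr7a3 (2.47), Ugdh (1.94) and Nqo1 (1.42). PPARα targets rose in 12 of 28 with 2 falling (14 and 3 adjusted over the list alone; adjusted p = 0.184 with an estimated correlation) and in 19 with 1 falling against medium (adjusted p = 0.0107 with an estimated correlation). Pdk4 rose by 2.39 (3.47 against medium), Cyp4a1 by 0.81 (3.31 against medium) and Cyp4a2 by 1.53 (3.34 against medium), while Fabp1 fell by 2.57 on the log2 scale (-0.13 against medium). The ATF4 list split, with 10 rising and 12 falling of 35 (10 and 13 adjusted over the list alone; median -0.19, mean 0.12). Wars (1.33), Trib3 (0.93; 0.02 against medium) and Ddit3 (0.89; -0.05 against medium) rose and Atf3 fell (-0.70). Against medium 3 rose and 18 fell (adjusted p = 0.13 with an estimated correlation). In the p53 list 2 rose and 4 fell of 21 (median -0.14, mean 0.02), with Plk2 at 0.97, Btg2 at -1.15, Mdm2 at 0.09 and Cdkn1a at -0.42, the last 2 not called. Hepatocyte genes rose in 9 and fell in 9 of 27 (median 0.20, mean -0.01), with Tat at 1.58, Fbp1 at 1.44, Hp at -2.95 and Alb, the albumin gene, at -1.02 (-0.34 against medium, adjusted p = 0.142). Against medium 16 rose and 3 fell (adjusted p = 0.131 with an estimated correlation).

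Other lists of NE at 10 mM did not pass against DMSO. AhR targets rose in 2 and fell in 2 of 6, CAR and PXR targets in 4 and 3 of 9, aldehyde and one-carbon metabolism in 6 and 2 of 16 and fatty acid synthesis in 2 and 5 of 15. Bile acid genes rose in 4 and fell in 1 of 10, hypoxia genes in 4 and 3 of 28, heat shock genes in 1 and 3 of 15 and metallothionein probes in 2 and 0 of 4. Oxidative phosphorylation rose in 2 of 21, Kupffer cell markers in 1 of 4 (Cd14, 1.53), stellate cell markers fell in 2 of 3 and cholangiocyte markers in 3 of 5, among them Sox9 (-1.57) and Krt19 (-0.82). Adjusted over the list alone hypoxia genes fell in 1, oxidative phosphorylation rose in 0 and cholangiocyte markers rose in 1, and the other counts of this group did not change. Endothelial, lymphocyte and erythroid markers had too few probes over the filter to be tested in any comparison. NE called 3557 probes at 10 mM (1634 up, 1923 down) and 750 at 3 mM (377 up, 373 down). At 3 mM the ATF4 list rose in 11 of 35 (22 adjusted over the list alone; adjusted p = 0.00149 with an estimated correlation), with Cth at 1.72 and Trib3 at 1.15 (0.25 against medium), and in 3 with 1 falling against medium (adjusted p = 0.319). Cell cycle genes fell at 3 mM in 10 of 21 (16 adjusted over the list alone; adjusted p = 0.0018 with an estimated correlation), among them Aurkb (-1.68) and Mcm3 (-1.51).

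**Figure D2:**
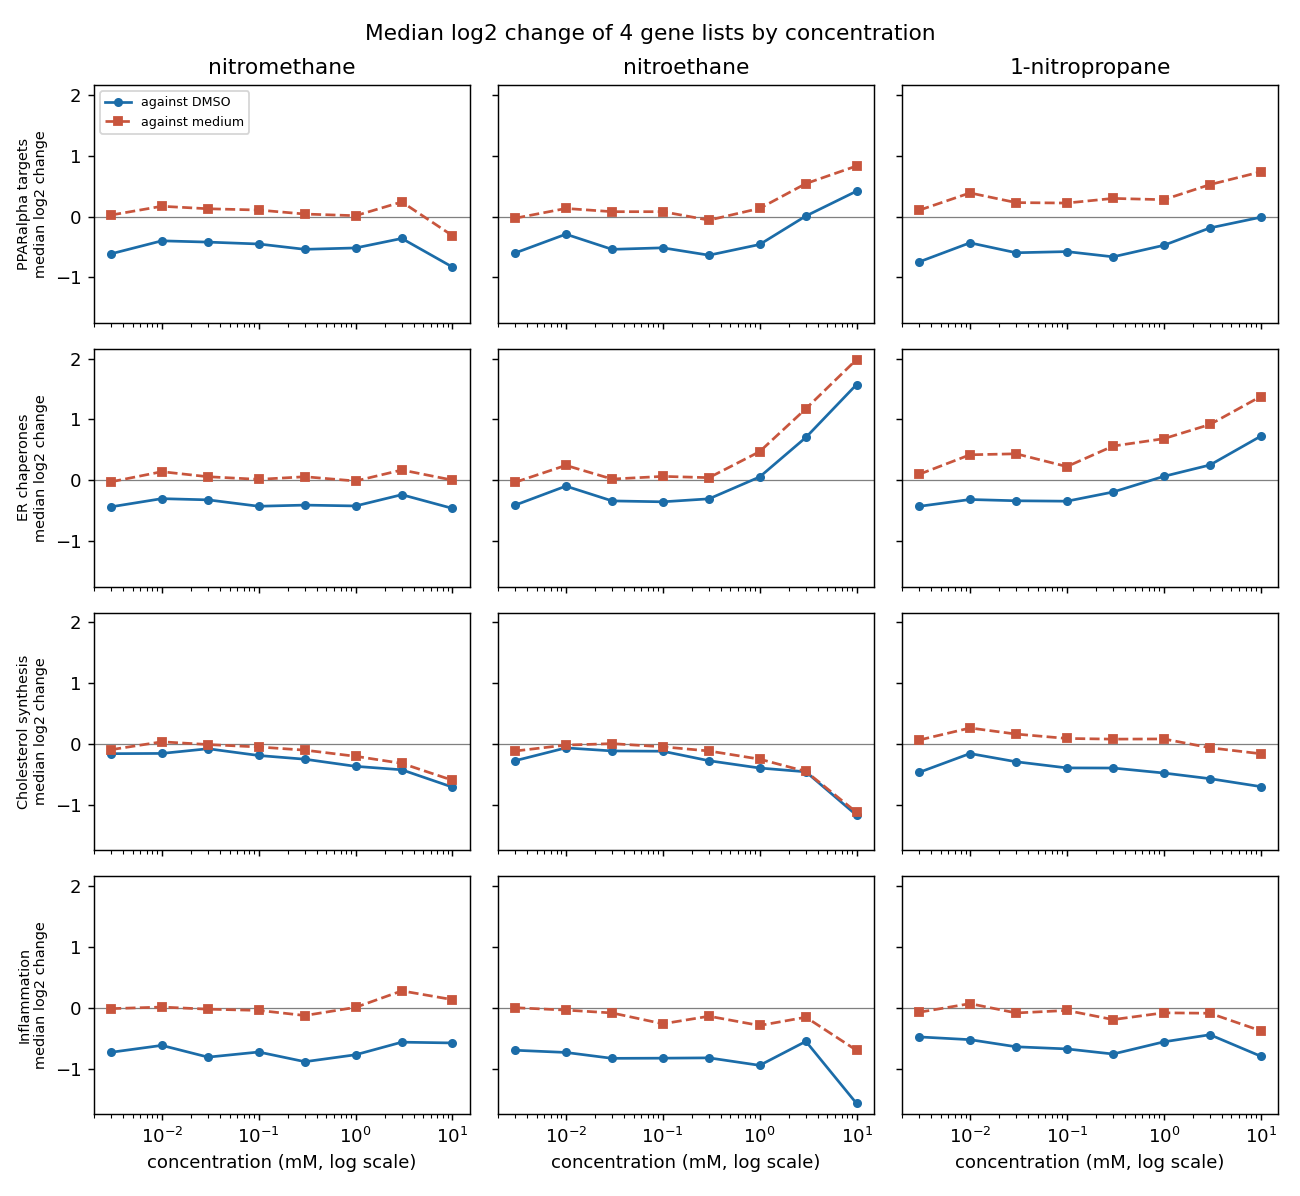
Median log2 change of the probes of 4 gene lists (PPARα targets, ER chaperones, cholesterol synthesis, inflammation) against DMSO (solid lines) and against medium (dashed lines) at each concentration (mM, log axis) of NM, NE and 1NP. Against DMSO at 10 mM the ER chaperone median was 1.57 for NE, -0.46 for NM and 0.72 for 1NP, whose replicate 3 stood apart (Hspa5 at 10.7, 10.7 and 176 CPM).

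1NP at 10 mM lowered inflammation and acute phase genes against DMSO. Orm1 fell by 1.83 ± 0.22 (adjusted p = 2.05e-05), from 1410 ± 126 to 413 ± 120 CPM (-1.05 against medium, adjusted p = 0.00998), and the complement gene C3 by 1.76 ± 0.27 (-1.0 against medium, adjusted p = 0.0252). A2m fell by 2.44 ± 0.42 (-0.49 against medium), the immediate early gene Egr1 by 2.27 ± 0.23 (-0.27 against medium) and Bace2 by 1.79 ± 0.37 (-1.22 against medium, adjusted p = 0.0394). In replicates 1, 2 and 3 C3 measured 711, 641 and 173 CPM, A2m 1450, 1700 and 241, and Bace2 13.1, 13.2 and 2.34. Replicate 3, which stood apart, thus deepened these falls, while replicates 1 and 2 also lay below the DMSO means (1640, 5840 and 31.3 CPM). Fabp1 did not stand apart by as much. Inflammation genes fell in 8 of 16 (10 adjusted over the list alone; adjusted p = 0.00106 with an estimated correlation), and in 1 of 16 against medium (adjusted p = 0.452 with an estimated correlation). Cxcl10 (-2.44), Plg (-2.21), Fabp1 (-1.88) and Cxcl9 (-1.79) fell against DMSO and were at 0.21, 0.13, 0.37 and 0.10 against medium. Plagl1 fell by 2.13 (-1.03 against medium, adjusted p = 0.0555).

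Among the rises of 1NP at 10 mM, Nefm (3.04 ± 0.38; 1.59 against medium, adjusted p = 0.0115), Calml4 (1.64 ± 0.30; 1.27 against medium, adjusted p = 0.0181) and Ptgr1, a reductase and NRF2 target (1.58 ± 0.37; 1.32 against medium, adjusted p = 0.0329), passed with both controls. Inhba (2.28), Lgals4 (2.26), G0s2 (2.24 ± 0.48), Crip1 (1.82), Pycr1 (1.74), Akr1b8 (1.69 ± 0.27) and Lgals1 (1.51) rose against DMSO and did not pass against medium, where they were at 0.20, 0.48, 0.73, 0.05, 1.16, 0.53 and 0.12. G0s2, Ptgr1 and Pycr1 did not pass without 1NP replicate 3 (0.81, 0.48 and 0.48), nor without any 1 of the DMSO libraries, and Bace2 did not pass without DMSO replicate 6 (-1.62). Calml4 measured 51.7, 58.4 and 132 CPM in replicates 1, 2 and 3, so replicate 3 adds to its rise, and Nefm was at 36.4 ± 23.7 CPM. For single genes the calls against medium without replicate 3 are not given here. Cholesterol synthesis fell in 6 of 21 (15 adjusted over the list alone; adjusted p = 0.0244 with an estimated correlation), with Lss at -0.88 and Sqle at -1.14 (-0.16 against medium), and in 0 of 21 against medium. Called by the preset correlation alone were hepatocyte genes (1 rose and 9 fell of 27; adjusted p = 0.191 with an estimated correlation), NRF2 targets (3 rose and 1 fell of 28; adjusted p = 0.441), the ATF4 list (4 rose of 35; adjusted p = 0.347), metallothionein probes (0 of 4; adjusted p = 0.441) and PPARα targets (1 fell of 28; median -0.01, mean 0.02; adjusted p = 0.753). Adjusted over the list alone the rises and falls were 2 and 10, 10 and 1, 7 and 0, 0 and 0, and 0 and 1. ER chaperones had a median of 0.72 with 0 of 16 called (adjusted p = 0.715 with an estimated correlation), and 7 of 16 rose against medium (14 adjusted over the list alone; adjusted p = 0.531 with an estimated correlation). These values rest on group means in which replicate 3 differed, as the next paragraph gives for Hspa5, Creld2 and Hyou1. Alb was at -1.02 (-0.23 against medium).

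Replicate 3 of 1NP at 10 mM stood apart from replicates 1 and 2 in some single genes and not in others. In replicates 1, 2 and 3 Hspa5 measured 10.7, 10.7 and 176 CPM (22.5 to 27.1 in DMSO of set 2), Creld2 67.9, 64.7 and 591, Hyou1 120, 159 and 1160, Tsku 43.2, 40.4 and 686, Cyp1a1 8.23, 8.28 and 137, Calcb 522, 430 and 8.91, and Cyp51 190, 208 and 53.3. Cyp1a2, at 3.64, 2.58 and 3.98 CPM, Aldh3a1, at 29.8, 24.2 and 36.3, and Fabp1, at 28.2, 25.4 and 34.3, did not stand apart by as much. Hspa5 differed by 1.40 ± 0.85 from DMSO (adjusted p = 0.49), Cyp1a1 by 2.41 (adjusted p = 0.163) and Pdk4 by 1.59 (adjusted p = 0.412). 1NP called 263 probes (125 up, 138 down), 586 without replicate 3, and 101, 142 and 131 without DMSO replicates 4, 5 and 6. Against medium it called 1237, and 82 without replicate 3. With only the 6 libraries compared in the fit, edgeR called 0 probes for 1NP (897 at an unadjusted p under 0.05) and 47 for NM at 10 mM, and DESeq2 in the fit of all doses called 410 for 1NP.

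**Figure D3:**
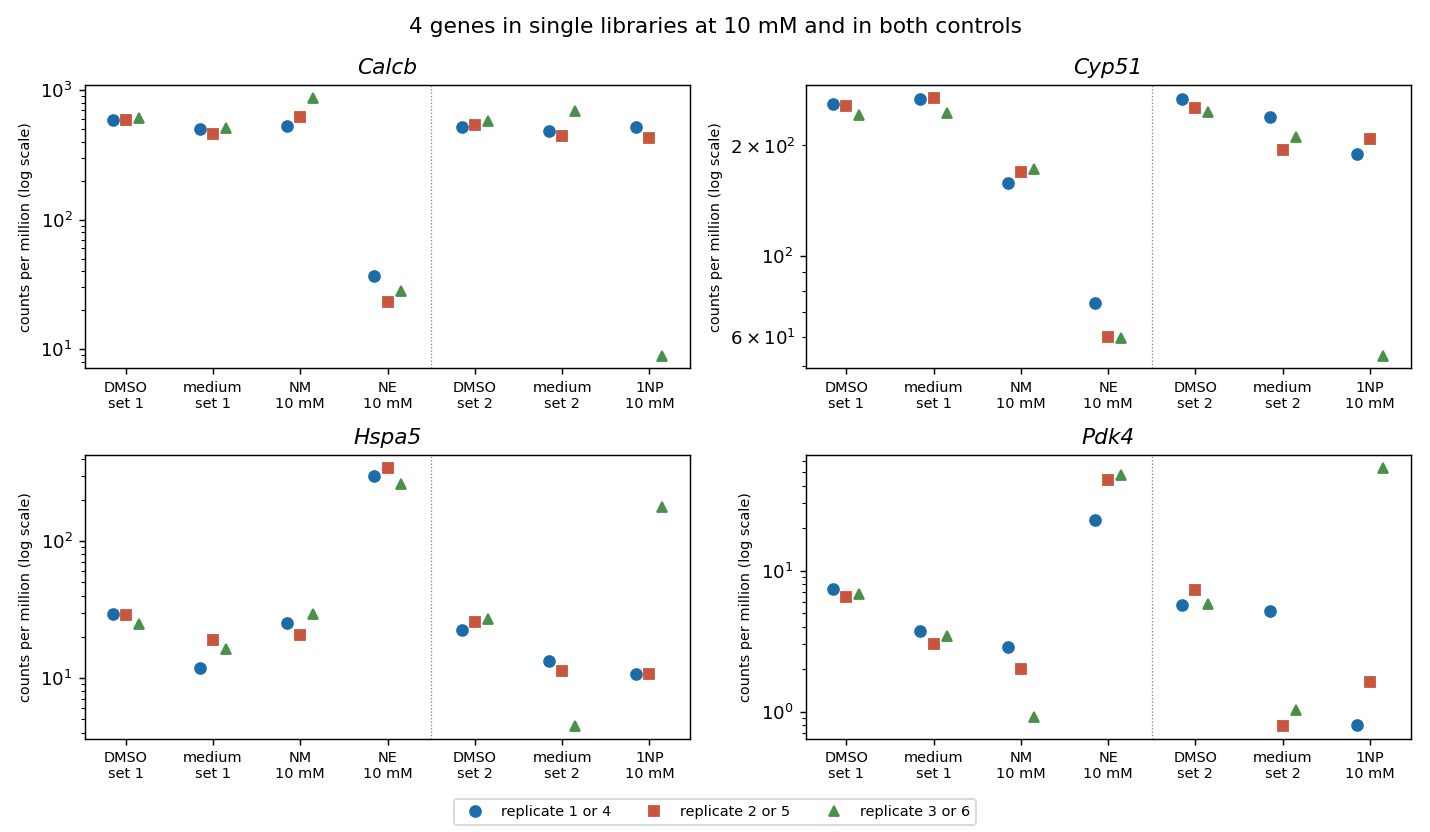
CPM (log axis) of Calcb, Cyp51, Hspa5 and Pdk4 in each library of DMSO and medium of both sets and of NM, NE and 1NP at 10 mM, with 1 marker per replicate. In 1NP Hspa5 measured 10.7, 10.7 and 176 CPM, and the NE mean was 301 CPM.

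A slope over the rank of concentration asked which probes moved steadily with dose, or with plate row, since the concentrations lay in rows A to H in order. It called 1377 probes for NM (1009 rising, 368 falling), 2638 for NE (1424 and 1214) and 109 for 1NP (82 and 27). With medium as control the counts were 1712, 3425 and 1368, and an omnibus test over the doses called 572, 4674 and 554. By DESeq2 the 1NP count was 226, and 575 over the 8 doses with no control. Without the 10 mM libraries it called 135, 326 and 5. The NM count was 316 without replicate 3 of 10 mM, and the NE count 1687 and 1709 without replicates 1 and 2 of 10 mM. The 1NP count was 183 without replicate 1 and 62 without replicate 3 of 10 mM. With no filter on low counts the NE slope called 9634 probes, in a fit that holds the replicate with 21627 detected probes.

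The nitroalkanes were compared with each other at matched concentrations to ask whether chain length changes the response. At 10 mM, NM cells had far less Cyp4b1 than NE cells (-6.58 ± 0.41, NM minus NE, adjusted p = 0.000321), 0.266 against 26.5 CPM. The NM libraries held 3 or fewer counts of it, so the size of the fold is uncertain. Bhlha15 (-4.38), Pdk4 (-4.30; 95% interval -5.22 to -3.39), Selenom (-3.64) and Cyp4a2 (-3.63 ± 0.24) were also lower with NM, as were Hspa5 (-3.63; -4.05 to -3.21), Cyp1a1 (-2.64; -3.68 to -1.59, adjusted p = 0.0159), Nqo1 (-1.30; -1.77 to -0.83) and Hmox1 (-1.05; -1.45 to -0.66). NM cells had more R3hdml (4.73 ± 0.33), the matrix protein gene Tnc (4.70 ± 0.33), the filament gene Nes (4.54), Calcb (4.46 ± 0.32; 677 ± 178 against 29.3 ± 7.08 CPM) and the transcription factor Etv4 (4.13). No difference was called for Ddit3 (0.01; -0.47 to 0.49), Mdm2 (0.25; -0.10 to 0.60), Cdkn1a (0.52; -0.22 to 1.26), Gclm (-1.07; -2.15 to 0.02) or Alb (0.28; -0.16 to 0.71). A p that misses the threshold does not show that the compounds act alike, and the intervals give the differences still allowed.

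NM and NE differed in 1352 probes at 10 mM (720 higher with NM, 632 lower), and in 4577 without the libraries that stood apart. Leaving out 1 library gave 863, 659 and 2711 without NM replicates 1, 2 and 3, and 440, 832 and 436 without NE replicates 1, 2 and 3. At 3 mM 2 probes passed, the ER chaperone gene Hyou1 (-1.68 ± 0.16, adjusted p = 0.0265; 172 against 531 CPM) and LOC103694875 (-4.32 ± 0.29), both chosen after their values were seen. The 3 mM count was 180 without NM replicate 1, 0 without NE replicate 1, 1 without each of the other 4 libraries and 0 with the replicate number as a block. At 0.03 mM 1 probe passed, Ccndbp1 (-1.10 ± 0.16, adjusted p = 0.00331), chosen in the same way. That count was 0 without NM replicate 1 or NE replicate 2, 4 without NM replicate 2 and 260 without NM replicate 3. At 0.003, 0.01, 0.1, 0.3 and 1 mM edgeR called 0 probes, with 480, 346, 1264, 947 and 201 at an unadjusted p under 0.05 where chance gives 559 to 572, and DESeq2 called 0, 0, 44, 0 and 3. At 0.1 mM the edgeR count was 88 without NM replicate 3.

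The effect of 1NP against its DMSO was compared with those of NM and NE against theirs. At 10 mM, 1NP minus NM was 1.64 for Hspa5 (95% interval -0.61 to 3.90), 2.13 for Cyp1a1 (-0.47 to 4.72), 3.49 for Pdk4 (0.44 to 6.53, adjusted p = 0.743) and -0.28 for Mdm2 (-0.65 to 0.09). 1NP minus NE was -1.98 for Hspa5 (-4.43 to 0.47), -0.50 for Cyp1a1 (-3.09 to 2.09), -0.92 for Asns, which makes asparagine (-1.51 to -0.33, adjusted p = 0.2), and 1.01 for Cdkn1a (0.24 to 1.78, adjusted p = 0.237). None of these passed after adjustment. In replicates 1, 2 and 3 of 1NP Pdk4 measured 0.81, 1.63 and 53.5 CPM, where DMSO of set 2 had 5.74 to 7.27. Hspa5 measured 10.7, 10.7 and 176 CPM, where that DMSO had 22.5 to 27.1. For both genes replicates 1 and 2 thus lay below DMSO and only replicate 3 above it. Their differences and intervals therefore do not show a change shared by the 3 libraries. At 10 mM edgeR called 0 probes in either comparison, with 611 and 1922 at an unadjusted p under 0.05 and 0 and 232 by DESeq2. Without 1NP replicate 3 the counts were 0 against NM and 3175 against NE. In simulated data of the same size these fits called 30 of 66 and 37 of 66 probes changed 4-fold.

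At lower concentrations the 1NP effect differed from the NM effect in 765 probes at 0.003 mM (235 up, 530 down) and 159 at 0.1 mM (66 up, 93 down). It differed from the NE effect in 101 at 0.003 mM (20 up, 81 down), 630 at 0.03 mM (230 up, 400 down) and 1809 at 0.1 mM (835 up, 974 down). With medium as control these counts were 1 and 0 against NM and 0, 0 and 3 against NE, and those of 0 held 1282, 604 and 928 probes at an unadjusted p under 0.05. Leaving out 1 library moved all 5. Against NM the 765 ran from 282 without NM replicate 2 to 1967 without 1NP replicate 3, and the 159 from 0 without 1NP replicate 2, DMSO replicate 5 or DMSO replicate 3 to 939 without 1NP replicate 3. Against NE the 101 fell to between 1 and 7 without any 1 of 9 of the 12 libraries, and was 1207 without 1NP replicate 3, 450 without NE replicate 1 and 180 without DMSO replicate 1. The 630 ran from 309 without DMSO replicate 5 to 1017 without DMSO replicate 1, and the 1809 from 1028 without DMSO replicate 3 to 2765 without 1NP replicate 3. At the other concentrations edgeR called 0 with DMSO as control, and with medium 250 against NM at 0.01 mM and 0 in the rest. Against NM the counts at an unadjusted p under 0.05 were 572, 1213, 714, 941 and 498 at 0.01, 0.03, 0.3, 1 and 3 mM, and DESeq2 called 1, 12, 2, 2 and 6. Against NE they were 764, 1096, 1259 and 842 at 0.01, 0.3, 1 and 3 mM, and DESeq2 called 3, 12, 8 and 11. Without 1NP replicate 3, the effects of 1NP and NE differed in 1155 probes at 1 mM and 444 at 3 mM. DMSO of set 2 differed from DMSO of set 1 in 1729 probes (889 and 840), so set and compound are joined in every comparison with 1NP. That count was 1139 and 980 without set 2 DMSO replicates 4 and 5, and 1087 without set 1 DMSO replicate 2.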

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

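Most tests of the 3 patterns weighed here were chosen only after the result was seen, namely those of the vehicle at 0.01 to 0.1 mM, of the plate row, of a nitroalkane effect at low dose, of 1NP replicate 3 and of an even background in NE replicate 2. The tests of the vehicle at 0.003 mM and of another cell type, and the counts over other splits of the libraries, were set beforehand.

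NM and NE, compared directly, differed in 1 probe at 0.03 mM, 2 at 3 mM and 1352 at 10 mM. Ccndbp1 differed by -1.10 at 0.03 mM, and Hyou1 by -1.68 and LOC103694875 by -4.32 at 3 mM (NM minus NE). At 10 mM R3hdml (4.73), Tnc (4.70), Nes (4.54), Calcb (4.46) and Etv4 (4.13) were higher with NM, and Cyp4b1 (-6.58, near the floor with NM), Bhlha15 (-4.38), Pdk4 (-4.30), Selenom (-3.64) and Cyp4a2 (-3.63) lower. The 1NP effect differed from the NM effect in 765 probes at 0.003 mM and 159 at 0.1 mM, and from the NE effect in 101, 630 and 1809 at 0.003, 0.03 and 0.1 mM. A difference between groups, tested directly, singled out each of these.

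At 0.003 to 0.1 mM all 3 nitroalkanes differed from DMSO, with Car3 at 3.27, 3.18 and 3.02 for NM, NE and 1NP at 0.003 mM. At 0.003 mM a difference of the DMSO libraries from wells without DMSO is consistent with the values: on the probes called for medium in the other set, the change was at least 1.05 times that of medium itself. From 0.01 to 0.1 mM that stays open, since NE at 0.03 and 0.1 mM had medians of 0.01 and 0.05 there, at the lowest 0.053 of the 0.19 of medium, with a spread over the probes that reaches it, and the references were mixed (WY-14643 of set 1 0.19, rifampin 0.10 and 0.17, CITCO 0.05 and 0.06, benzo[a]pyrene -0.05). The plate row as the whole cause is argued against, because the 0.01 mM wells, in the row of DMSO, still had at least 0.48 of the change of the 0.003 mM wells, in the row of medium, and so is a nitroalkane effect as the whole cause, because at most 0.19 of the median change of the called probes was left against medium over 12 comparisons. Open are a smaller effect of the lowest concentrations, and whether the nitroalkane wells held DMSO, which the labels do not say.

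1NP replicate 3 scored above replicates 1 and 2 at 1, 3 and 10 mM in the direction of NE at 10 mM. Its scores on the probes called for NE were 0.41, 0.47 and 1.09, where replicates 1 and 2 gave -0.09 to 0.23 over 16 libraries (SD 0.10). Only its 10 mM library met the measures for standing apart (median correlations with its group 0.955, 0.968 and 0.896). WY-14643 of set 2 scored 0.24 to 0.35 and benzo[a]pyrene 0.20 to 0.39, so 0.41 is little above other treatments. A swap with an NE 10 mM library is argued against, since their lowest score was 0.93, on probes called with these same libraries. A swap at a lower concentration was not tested, and at 3 mM NE replicates 1, 2 and 3 scored 0.50, 0.43 and 0.23. As the cause at all 3 doses 1 wrong label at 10 mM is argued against. At 1 mM replicate 3 of 1NP was also above the range of replicates 1 and 2 (0.41), if little above the 0.32 to 0.36 of DMSO of set 2. Depth or background of the 1NP 10 mM library is argued against by its total of 8534350, within 6873557 to 9711694 of the other 23 libraries. Its 13757 detected probes, under their highest of 16457, argue against it too. Another exposure and an effect of the plate column cannot be told apart, since replicate 3 had the highest score at 7 of 8 doses and the replicate number is the column. For the 10 mM library alone a wrong label cannot be excluded. Its score of 0.54 on the probes that separate the sets lies within the range of NE at 10 mM (-0.05 to 0.63) and of the rest of set 2 (0.51 to 1.85). Both ends of the second range are medium libraries, which also set the scale of the score. The other libraries of set 2 without medium scored 0.56 to 1.38, and replicates 1 and 2 of 1NP at 10 mM 1.02 and 1.14. Against these 0.54 would point to a wrong label, by a margin too small to decide. That 1NP acts like NE stays a hypothesis that 1 library carries.

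NE replicate 2 at 10 mM had counts in 93% of the 8606 probes with a median of 0, against 5.88% and 6.17% in replicates 1 and 3. RNA of another cell type is argued against, because 1049 probes of olfactory receptors, which liver cells do not use, had a median count of 14 against 12 over all those probes, a ratio of 1.17. An even background added to every probe is consistent with the 93% and with the 2.03% of reads in those probes, against 0.0124% in replicate 1. No other biological explanation was tested, and the source of the background stays open.

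Splits of 3 libraries against 3 number 10, too few for a share under 0.05. With that limit, 1 split of 10, the real one, gave as many probes in each comparison with DMSO. The real counts from the lowest concentration up were 474, 124, 216, 248, 384, 251, 83 and 879 for NM, 366, 330, 330, 424, 652, 346, 750 and 3557 for NE, and 2414, 49, 124, 616, 124, 180, 69 and 263 for 1NP. For the references they were 855 and 2769 for medium of sets 1 and 2, 1110 for benzo[a]pyrene, 18 and 102 for CITCO, 347 and 204 for rifampin, and 591 and 104 for WY-14643, and 1729 for DMSO between the sets. The highest other count was 1 for NM at 0.01 mM, 61 for 1NP at 10 mM, 4 for WY-14643 of set 1 and 0 for the rest. Between NM and NE it was 1 split of 10 at 3 and 10 mM (real 2 and 1352, highest other 0) and 4 of 10 at 0.03 mM (real 1, highest other 58, which points to a structure of those libraries). At 0.003, 0.01, 0.1, 0.3 and 1 mM the real count was 0, so 10 of 10 gave as many, with highest others of 2, 0, 1, 0 and 0.

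For the effects across sets and the slopes, 30 splits were drawn. For the 1NP against the NE effect at 0.003, 0.03 and 0.1 mM only the real split gave as many (1 of 30 each, real 101, 630 and 1809, highest others 0, 10 and 637). These splits exchange treated and DMSO libraries within a set. They ask whether a compound acted, not whether the effects of 1NP and NE are equal, so chance stays open for these differences. For the slopes of NM, NE and 1NP a random order of the libraries is argued against (1 of 30 each, real 1377, 2638 and 109, highest others 0, 15 and 6). Those draws exchange single libraries among all groups of a fit. Any lasting difference between groups, of DMSO, of a plate row or of 10 mM alone, could give the same outcome. A steady trend with dose was therefore not tested by them. A share of 1 of 30 is the smallest these draws can give. With medium as control the 3 counts against NE were 0, 0 and 3, and at 0.003 mM leaving out any 1 of 9 of the 12 libraries left 1 to 7 probes. Chance cannot be excluded either for the 1NP against the NM effect at 0.003 and 0.1 mM (3 of 30 each, real 765 and 159, highest others 1621 and 1528). A drawn split could keep the real labels of 1 set and exchange those of the other. A high count can then come from an effect left in, and it shows no structure of the libraries. With a real count of 0, 30 of 30 gave as many. The highest others there were 1, 145, 0, 478, 1 and 0 against NM at 0.01, 0.03, 0.3, 1, 3 and 10 mM, and 758, 1853, 2, 0 and 1426 against NE at 0.01, 0.3, 1, 3 and 10 mM. The high ones among these have the same limit.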

How the results depend on the processing

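Settings chosen after the data were seen are the 0.003 mM libraries as control, with and without a replicate block, the slope over 8 doses with no control, each setting without the libraries that stood apart, and medium as control for the lists. Medium as control was planned. The named genes gave 159 results, a gene in several comparisons counting once in each, for 81 names. Of 134 such results fitted with both controls, 51 kept their call and direction against medium, 58 kept the direction and lost the call, and 25 changed sign, of which 5 passed against medium. With DESeq2 size factors and with the DESeq2 test, 156 of 156 results kept both, and a replicate block left 130 of 130. With no filter 3 lost the call, in fits of only the libraries compared 32 of 146, and without the libraries that stood apart 4 of 88. Leaving out 1 library left 860 gene results and ended 76 calls, and none changed sign. DESeq2 size factors left all 61 counts of probes within 1.5 times. Where a fit left 2 libraries in a group, its spread was taken from the other groups too. For single probes depth sets a floor of 3 counts per library. In simulated data with 3 libraries per group a 2-fold change was called for 31 of 67 probes in NE at 10 mM and for 4 of 67 between NM and NE. Counts stand in the order of the concentrations, lowest first. The values outside 1.5 times the reported count follow, grouped by setting, and the cause was not tested except where the setting itself removes libraries or probes.

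With medium as control these genes changed sign from their value against DMSO, some to values near 0 that show no direction. Only Cxcl10 and C4bpb with CITCO at 10 µM, Hdc with rifampin at 40 µM, and Cps1 and Plg with WY-14643 of set 2 passed against medium. The genes were Hdc with NM at 10 mM (1.00) and with rifampin at 20 and 40 µM (1.15 and 1.39), Lgals4 with NM at 0.003 mM (-0.11) and Car3 with NE at 0.003 mM (0.00) and rifampin at 20 µM (-0.94). With 1NP at 10 mM they were Cxcl10 (0.21), Plg (0.13), Fabp1 (0.37) and Cxcl9 (0.10), and at 0.003 mM Cps1 (0.46). With CITCO at 10 µM they were Mmp2 (-0.49), Nefl (-0.38), Cxcl10 (1.42) and C4bpb (1.49), and at 20 µM Fabp1 (0.97). With rifampin at 20 µM they were also Mmp2 (-0.04), Lpl (0.33) and Bhmt (0.39), and at 40 µM Mmp2 (-0.17), Fblim1 (-0.01) and Plg (0.14). With WY-14643 they were Bhmt (0.56) in set 1 and Cps1 (1.5) and Plg (0.88) in set 2. The cause was not tested.

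With medium as control, NM gave 0, 0, 0, 0, 0, 1, 284 and 81 over the 8 concentrations. NE gave 0, 2, 0, 0, 4, 27 and 1423 from 0.003 up to 3 mM. 1NP gave 1, 23, 0, 2, 0, 8, 27 and 1237 over the 8 concentrations. The slope gave 1368 for 1NP. Benzo[a]pyrene gave 2382, CITCO at 10 µM gave 312, CITCO at 20 µM gave 1785, rifampin at 20 µM gave 33, rifampin at 40 µM gave 401 and WY-14643 of set 2 gave 1954. The 1NP effect gave 1, 250 and 0 at 0.003, 0.01 and 0.1 mM against that of NM and 0, 0 and 3 at 0.003, 0.03 and 0.1 mM against that of NE. The numbers of lists called were those of NM at 10 mM (5), NE at 10 mM (14), rifampin at 20 µM (7) and WY-14643 of set 2 (13). Medium as control without those libraries gave 0, 57, 10, 29, 16, 11, 545 and 275 over the 8 concentrations for NM, 0, 0, 0, 0, 18, 149 and 2207 from 0.003 up to 3 mM for NE, and 1, 283, 35, 4, 340, 49, 537 and 82 over the 8 concentrations for 1NP.

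The 0.003 mM libraries as control gave 2, 0, 0, 0, 1, 379 and 221 from 0.01 mM up for NM, 0, 0, 0, 15, 37 and 1421 from 0.01 to 3 mM for NE, and 9, 0, 0, 464, 0, 33 and 1841 from 0.01 mM up for 1NP. That control with a replicate block gave 0, 0, 0, 0, 1, 285 and 108 from 0.01 mM up for NM, 0, 0, 0, 3, 28 and 1358 from 0.01 to 3 mM for NE, and 253, 1, 1, 961, 8, 180 and 2106 from 0.01 mM up for 1NP. Fitted with only the libraries compared, NM gave 1481, 720, 830, 660, 963, 33, 0 and 47 over the 8 concentrations. NE gave 930, 2, 1818 and 1828 at 0.003, 0.01, 0.03 and 0.1 mM. 1NP gave 3826, 1385, 2042, 2750, 1269, 66, 440 and 0 over the 8 concentrations. Benzo[a]pyrene gave 717, CITCO at 10 µM gave 46, rifampin at 20 µM gave 665 and WY-14643 of set 2 gave 310.

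Leaving out the libraries that stood apart, NM gave 1361, 692, 901, 1253, 1212, 676, 295 and 1376 over the 8 concentrations. The slope gave 374 for NM and 62 for 1NP. NE gave 695, 217, 698, 760, 1257, 723 and 1483 from 0.003 up to 3 mM. 1NP gave 189, 464, 1585, 416, 789, 404 and 586 from 0.01 mM up. NM against NE gave 7, 180 and 4577 at 0.01, 3 and 10 mM. The 1NP effect gave 1 and 50 at 3 and 10 mM against that of NM and 1 and 4312 at 0.01 and 10 mM against that of NE.

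With no filter on low counts, NM gave 80 and 44 at 0.01 and 3 mM. NE gave 863 at 0.01 mM. The slope gave 9634 for NE and 257 for 1NP. CITCO at 10 µM gave 102, CITCO at 20 µM gave 295, rifampin at 20 µM gave 531, rifampin at 40 µM gave 499 and WY-14643 of set 2 gave 196. NM against NE gave 1, 45, 138 and 14 at 0.003, 0.03, 0.1 and 3 mM. The 1NP effect gave 8, 84, 631, 6 and 1 from 0.01 to 0.3 and at 3 mM against that of NM and 645, 171, 2 and 753 at 0.003, 1, 3 and 10 mM against that of NE.

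By the DESeq2 test, NM gave 248, 351, 396, 416 and 244 at 0.01, 0.03, 0.1, 1 and 3 mM. NE gave 550, 676, 548 and 528 at 0.003, 0.01, 0.03 and 1 mM. 1NP gave 119, 248, 1043, 238, 447, 232 and 410 from 0.01 mM up. The slope gave 226 for 1NP. CITCO at 10 µM gave 51, CITCO at 20 µM gave 179, rifampin at 40 µM gave 333 and WY-14643 of set 2 gave 163. NM against NE gave 2, 44, 3, 119 and 2040 at 0.03, 0.1, 1, 3 and 10 mM. The 1NP effect gave 1, 12, 436, 2, 2 and 6 from 0.01 to 3 mM against that of NM and 460, 3, 12, 8, 11 and 232 at 0.003, 0.01, 0.3, 1, 3 and 10 mM against that of NE. A replicate block gave 32 for CITCO at 10 µM and 3, 45, 0 and 575 at 0.03, 0.1, 3 and 10 mM for NM against NE. An omnibus test over the doses in place of the slope called 572 for NM, 4674 for NE and 554 for 1NP. Without the 10 mM libraries, the slope gave 135 for NM, 326 for NE and 5 for 1NP. Over 8 doses with no control, the slope gave 575 for 1NP. With an estimated inter-gene correlation, the numbers of lists called were those of NM at 10 mM (9), NE at 10 mM (3), 1NP at 10 mM (2), CITCO at 10 µM (2), CITCO at 20 µM (2), rifampin at 20 µM (9), rifampin at 40 µM (5) and medium of set 2 (6).

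Leaving out 1 library at a time gave these lowest and highest counts. NM 245 to 432, 45 to 126, 106 to 168, 118 to 208, 207 to 314, 133 to 200, 20 to 76 and 498 to 1001 over the 8 concentrations. The slope gave NM 316 to 1873, NE 1687 to 2936 and 1NP 62 to 183. NE 162 to 332, 74 to 1170, 147 to 235, 213 to 288, 368 to 486, 150 to 244, 356 to 823 and 2495 to 3471 over the 8 concentrations. 1NP 898 to 2303, 13 to 22, 32 to 61, 135 to 866, 52 to 76, 41 to 1858, 21 to 69 and 101 to 586 over the 8 concentrations. Medium of set 1 510 to 787, benzo[a]pyrene 751 to 1079, CITCO at 10 µM 4 to 11, CITCO at 20 µM 37 to 79, rifampin at 20 µM 107 to 283, rifampin at 40 µM 79 to 192, WY-14643 of set 1 246 to 964, medium of set 2 1561 to 4106, WY-14643 of set 2 67 to 90 and DMSO of set 1 against that of set 2 980 to 1790. NM against NE 0 to 2, 0 to 7, 0 to 260, 0 to 88, 0 to 1, 0 to 0, 0 to 180 and 436 to 2711 over the 8 concentrations. The 1NP against the NM effect 282 to 1967, 0 to 1, 0 to 25, 0 to 939, 0 to 1, 0 to 148, 0 to 1 and 0 to 0 over the 8 concentrations. The 1NP against the NE effect 1 to 1207, 0 to 1, 309 to 1017, 1028 to 2765, 0 to 172, 0 to 1155, 0 to 444 and 0 to 3175 over the 8 concentrations.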

Other observations

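The changes from 0.003 to 10 mM and the scores on the probes that separate the sets were chosen after the results were seen. NE at 10 mM also changed single genes beside those already described, all from lists that did not pass as lists against DMSO. Scd, which makes monounsaturated fatty acids, fell by 2.17 on the log2 scale (-1.68 against medium), Dgat2 by 2.08 (-1.97) and Fasn by 1.27 (-1.42), while the regulator Srebf1 rose by 1.36 (1.42; NE against DMSO, n = 3 each, with the value against medium in parentheses from here on). The bile acid importer Slc10a1 rose by 2.06 (3.05) and Akr1d1 by 1.10 (2.95), and Fgfr4 fell by 1.52 (-1.08). Sult1a1, a sulfotransferase, rose by 1.85 (1.61), Dao by 1.26 (1.09) and Aldh1a1 by 0.87 (1.69), and the peroxidase Gpx1 fell by 1.66 (-1.79). The growth factor Vegfa rose by 1.52 (1.43) and the mitochondrial chaperone Hspd1 by 1.23 (1.54). Metallothionein Mt2A rose by 1.30 (2.84). Apoc3 fell by 2.25 (-1.32).

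NM at 3 mM showed another picture against medium than against DMSO. Cyp2b2, a CAR target, was at 1.01 against DMSO (adjusted p = 0.169) and rose by 3.10 against medium (adjusted p = 3.13e-05), and Cyp4a1 rose by 1.98 against medium (adjusted p = 0.00217). Cxcl10 fell by 1.17 against DMSO and rose by 1.36 against medium (adjusted p = 0.0031). Insig1 fell by 0.90 against DMSO and was at -0.74 against medium (adjusted p = 0.0182). Replicate 1 at 3 mM, with 14783 detected probes, stood apart in this group.

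The change from 0.003 to 10 mM within each compound subtracts no control library. The DMSO libraries of the set were in each fit for filter, scaling and spread, so the fits of NM and NE share them. In every compound it is also a change from plate row A to row H, and a row effect common to the compounds was not tested. Across 11994 probes the changes of NE and 1NP had Pearson r = 0.61 and Spearman rho = 0.65, across genes, which are not independent replicates. Of the called probes 814 rose with both where chance gives 204, 426 fell with both where chance gives 135, and 2 moved in opposite directions. For NM and NE the values were r = 0.23 and rho = 0.23 across 12093 probes, with 103 shared rises where chance gives 33.3, 15 shared falls where chance gives 6.64, and 28 in opposite directions. For NM and 1NP they were r = 0.17 and rho = 0.17 across 11955, with 113 shared rises where chance gives 17.5, 6 shared falls where chance gives 2.06, and 1 in opposite directions. The libraries of 1NP include replicate 3, and the correlation was not computed without it.

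Libraries of NM that stood apart scored in the direction of set 2 on 739 probes that separate the DMSO libraries of the sets, at 2.89 for replicate 3 at 10 mM, 2.67 for replicate 1 at 3 mM and 1.66 for replicate 1 at 1 mM. The DMSO libraries of set 2 scored 1.00 to 1.3 and its 1NP libraries 0.54 to 1.38. Its medium libraries, which help to set the scale, scored 0.51, 0.64 and 1.85. The NM scores at 10 and 3 mM lay above every library of set 2, so they do not show a likeness to that set.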
